A study of Rattus norvegicus with 6 samples.

How the data were processed

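RNA from the renal cortex of 6 male Sprague-Dawley rats was measured on 1-colour Agilent microarrays, 1 array per animal. Per the labels' protocols, 3 animals received corn oil for 4 weeks and 3 received tricresyl phosphate at 200 mg/kg/day for 4 weeks, so the replicates are separate animals. Complementary RNA was labelled with the dye Cy3.

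The authors scanned and quantified the arrays with Agilent Feature Extraction, version 10.7 per the submitters' processing notes and 10.7.1.1 per the file headers. The deposited intensity values used here are linear: a processed signal, which is the spot brightness after subtraction of local background and spatial detrending within the array, and the median brightness of each spot and of its background. Flags set by the same software mark spots well above background, outlier spots and saturated spots. The authors' value table holds a further intensity per probe. Over the brighter probes of the same array, each of its columns equals the processed signal divided by 1 number per array. The coefficient of variation of that ratio lay between 0.0174% and 0.0212%, and the dimmer probes were left out of this check. Its scale is therefore linear, uncentred and scaled to the 75th percentile, and the column medians lie between 0.1094 and 0.1151. The software that made this scaling is not given in the sources used here.

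Each array carries 61537 non-control probes with 1 spot each and 1439 control spots, which were left out. Between 41503 and 43823 probes per array were well above background. No spot was saturated and 77 outlier spots over all arrays were set missing. The number of arrays limits the precision of every value. Probes were named by matching the accession in the scanner files, without its version, to the RefSeq gene table of assembly GRCr8. A single symbol was found for 28206 probes, several symbols for 0 and none for 33331. The arrays were annotated by the authors on another build, rn4 per the file headers, so no coordinates are given.

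Values were log2 processed signals minus the 75th percentile of the same array over non-control probes, and levels below are on this scale. A probe was kept if it was well above background on at least 3 of the 6 arrays, which kept 43099 probes and removed 18438. Each gene was represented by the kept probe with the highest mean level, which gave 31637 genes, unnamed transcripts or unnamed probes, called genes below, 12432 of them with a symbol. The kept probes include 7 with ERCC names, which mark spike-in controls, and 639 whose names start with C_CA, all marked as non-control in the files. Of 6504 symbols with several kept probes, 2715 had probes with differences of opposite sign, and in 2 of these both signs reached an unadjusted limma p under 0.05. The groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of adjusted p under 0.05. Errors given as SE come from this fit.

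Gene lists for pathways and cell types, 41 in all with 934 genes, of which 929 had a current symbol, were tested with camera of limma at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 41 lists. Beside it stand camera with a correlation estimated from the arrays and fry, whose directional p asks whether the members move one way on balance without comparing them with other genes. Medians of lists were set against 10000 random lists of equal size matched on signal level. The lists, groups, test, rule for named genes and all alternatives but 2 were fixed before the data were examined.

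The genes named were to be the 12 largest rises and falls among genes with a symbol past the threshold and with groups that do not overlap. Because fewer than 5 passed in either direction, the 5 with the smallest p in each direction are given and said not to pass. Predicted loci were skipped. Beside these stand the 4 members with the smallest p of each list past the threshold, and 19 genes named whatever their values, some of which are not reported here. Where a gene was not well above background on any array of 1 group, its difference is a bound: the brighter group's mean against the mean, per array, of the higher of the probe's own level and the lowest level among probes well above background.

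The alternatives were other normalizations, normexp background correction with an offset of 50 followed by quantile normalization (called normexp below), the authors' value table, other filters on dim probes, other treatments of several probes and outlier spots, other variance models, other thresholds, the slide as a block, the replicate number as a block and leaving out each array. The mean spot signal named in the plan for normexp was not used here, and the median spot signal took its place. Corn oil replicate 1 lay alone on slide 1 and scan 1, and the other 5 arrays on slide 2 and scan 2. A slide block therefore equals the comparison of the 5 arrays on the shared slide.

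The gene test was tested on simulated data for the comparison of tricresyl phosphate with corn oil. The 31637 genes had the measured means, and variances drawn from the prior distribution that limma fitted. Genes were independent and variances did not depend on signal level, so the limma model held by construction. The rates below do not describe dim or bright genes apart. At an adjusted p under 0.05 it recovered 2 of 67 genes changed by 0.5 on the log2 scale, 26 of 67 changed by 1 and 56 of 66 changed by 2, and called 7 of 31437 unchanged genes. In simulated lists of 20 genes with no shift and independent members, 1.5% reached an unadjusted camera p under 0.05. With a correlation of 0.1 between members, 21% of unshifted lists did so at the preset correlation and 2% with an estimated one. Of lists shifted by 0.3 on the log2 scale with that correlation, 100% did so at the preset correlation and 84% with an estimated one. Correlations above 0.1 were not simulated.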

Results

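Gene expression was measured in the renal cortex of 6 male rats, 3 given the vehicle corn oil and 3 given tricresyl phosphate, an organophosphate ester used as a plasticiser and flame retardant. The median processed signal per array ranged from 102.6 to 133.2 over a median local background of 33.0 to 41.0. Correlations between arrays over all genes ranged from 0.988 to 0.990 within groups and from 0.987 to 0.991 between groups. The comparison asks which transcripts of the renal cortex differ after 4 weeks of tricresyl phosphate.

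No single gene passed the threshold. The lowest p belonged to Galnt3, which encodes an enzyme that starts mucin-type O-glycosylation. Its level was 1.76 ± 0.05 (SD, n = 3) with corn oil and 0.58 ± 0.07 (SD, n = 3) with tricresyl phosphate. The difference was −1.18 ± 0.085 (SE) on the log2 scale, 0.44-fold, with an adjusted limma p of 0.118. Acsm3, a mitochondrial medium-chain acyl-CoA synthetase of the proximal tubule, was at 3.999 ± 0.25 (SD, n = 3) with corn oil and 2.53 ± 0.19 (SD, n = 3) with tricresyl phosphate. Its difference was −1.47 ± 0.16 (SE), with an adjusted limma p of 0.515.

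Of the 31637 genes tested with limma, 0 were higher and 0 lower at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1737, with 517 higher and 1220 lower, against 1582 expected by chance. Other splits of the 6 animals into 3 and 3 gave between 1141 and 2002 such genes, and 2 of them gave more than the real one. Over all genes tested the median difference was −0.038 on the log2 scale, so more genes were lower than higher. The share of genes that were lower ranged from 50.6% to 76.0% over 5 classes of signal level, and was highest in the brightest class. Counts of higher and lower genes here, and of list members below, take no account of this shift. The groups did not overlap in 3727 genes, or 11.8%, where chance gives 10%. Normexp background correction followed by quantile normalization gave 2 genes, Galnt3 and the unnamed transcript ENSRNOT00000040702, where quantile normalization alone gave 0. A variance model with an intensity trend and robust estimation gave the same 2. Without tricresyl phosphate replicate 3 the transcript passed, and without tricresyl phosphate replicate 2 Zp2, a zona pellucida gene not well above background on the remaining tricresyl phosphate arrays, passed. The transcript and Zp2 were singled out after their values were seen. The transcript had a difference of −2.92 ± 0.21 (SE) and an adjusted limma p of 0.118.

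Among the other genes with the smallest p, Kif15, a mitotic kinesin, differed by −1.28 ± 0.17 (SE). Layn, which encodes a hyaluronan-binding membrane protein, differed by −0.69 ± 0.11 (SE). The olfactory receptor gene Or8k39 was not well above background on any tricresyl phosphate array and was at least 1.86-fold lower there. In the other direction, Pheta2, which encodes a protein of endosomal trafficking, differed by 1.74 ± 0.20 (SE), and was well above background on 2 of the 3 corn oil arrays. Oit3 differed by 1.19 ± 0.17 (SE) and Fut9, a fucosyltransferase, by 0.71 ± 0.13 (SE). Catsperg, a subunit of a sperm calcium channel, differed by 0.56 ± 0.11 (SE), with its other probe at 0.21. Gfm2, a mitochondrial elongation factor, differed by 0.54 ± 0.09 (SE). Adjusted limma p-values of these 8 genes lay between 0.515 (Pheta2) and 0.811, so none passed. Their 3 values in one group all lay outside the range of the other group.

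**Figure D1:**
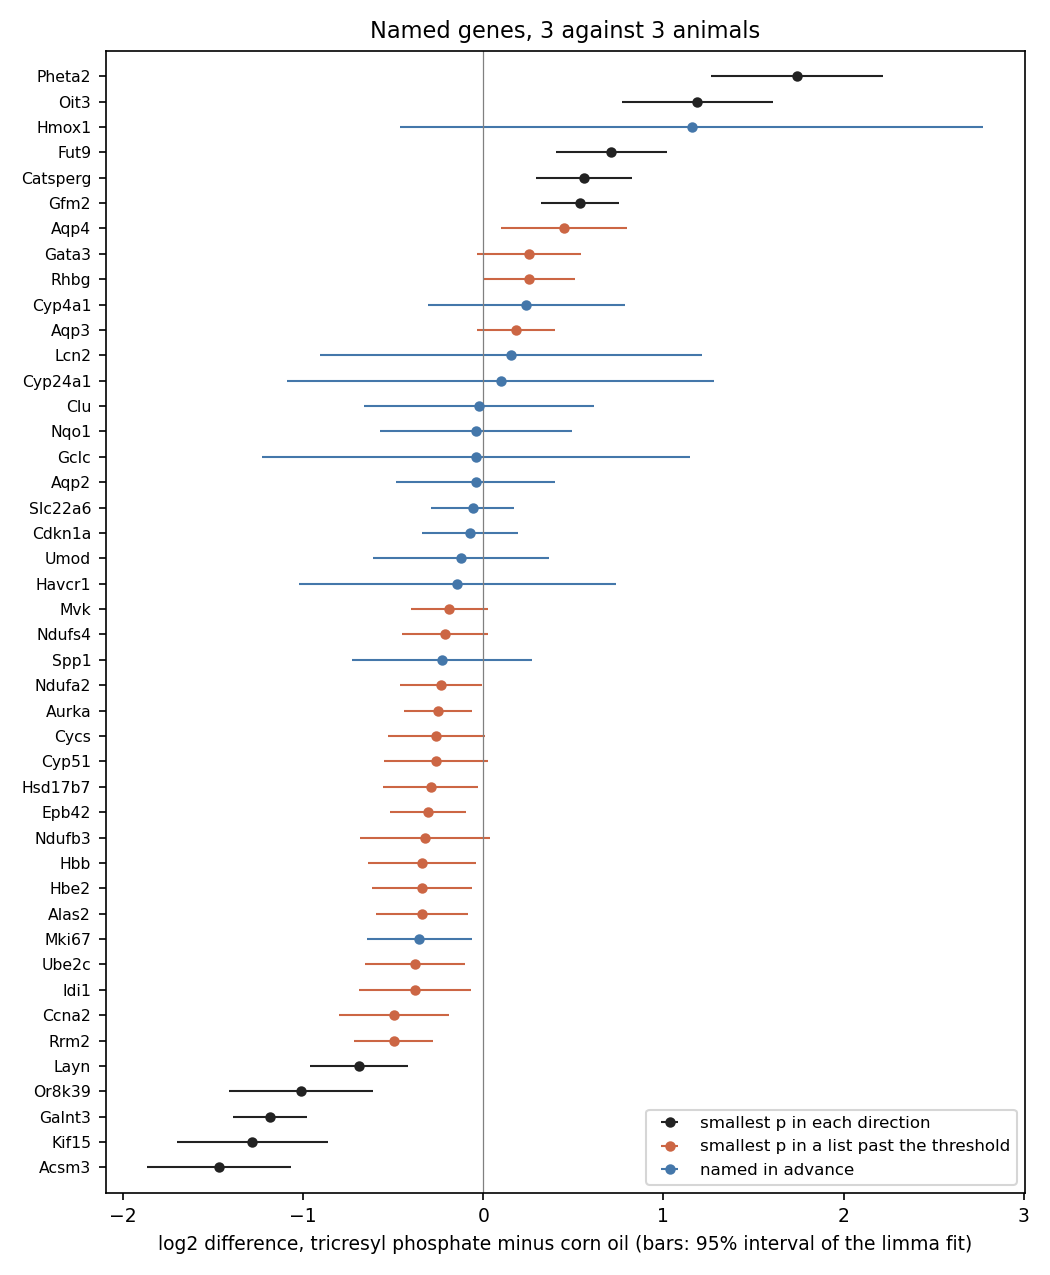
Log2 difference between 3 tricresyl phosphate and 3 corn oil animals for each named gene, with bars for the 95% interval of the limma fit. Galnt3 at −1.18 has a narrow interval, Hmox1 at 1.16 has one that spans 0, and no gene passed the adjusted threshold.

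Cell cycle genes were lower as a group with tricresyl phosphate. Of 29 measured members 25 were lower, with a median difference of −0.21 on the log2 scale, and the list passed camera with an adjusted p of 9.49e-05. The call was lost when the correlation between members was estimated (adjusted p = 0.671 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, was at 1.07 ± 0.08 (SD, n = 3) with corn oil and 0.58 ± 0.08 (SD, n = 3) with tricresyl phosphate. Ccna2, the S and G2 phase cyclin, differed by −0.50 ± 0.13 (SE), Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, by −0.38 ± 0.11 (SE), and the mitotic kinase gene Aurka by −0.25 ± 0.08 (SE). Mki67, the proliferation marker named in advance, differed by −0.35 ± 0.12 (SE). Over all genes 0 members passed, and adjusted over the list alone 1 fell, Rrm2. Probes of 1 gene differed: the 4 of Rrm2 ranged from −0.50 to −0.004, those of Ccna2 from −0.50 to 0.03 and those of Mki67 from −0.35 to 0.01. Within the shared slide the median of the list was −0.27 and the adjusted camera p 4.11e-07.

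Genes of cholesterol biosynthesis and uptake were lower as a group with tricresyl phosphate. Of 26 measured members 23 were lower, with a median of −0.15 and an adjusted camera p of 0.00204 (adjusted p = 0.671 with an estimated correlation). Idi1, the isomerase of isopentenyl diphosphate, differed by −0.38 ± 0.13 (SE), and Hsd17b7, a sterol reductase of the pathway, by −0.29 ± 0.11 (SE). Cyp51, the lanosterol demethylase, differed by −0.26 ± 0.12 (SE), with its probes at −0.26 and −0.03, and the mevalonate kinase gene Mvk by −0.19 ± 0.09 (SE). No member passed over all genes or adjusted over the list alone. Within the shared slide the median was −0.14 with an adjusted camera p of 0.00256, and without tricresyl phosphate replicate 2 the adjusted p was 0.0925.

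Collecting duct markers were higher on balance with tricresyl phosphate, though the animals of both groups overlapped. The mean list level of corn oil replicate 3, 0.085, lay above those of tricresyl phosphate replicates 1 and 3, 0.065 and −0.007. Of 19 measured members 14 were higher, with a median of 0.13 and an adjusted camera p of 0.00065 (adjusted p = 0.671 with an estimated correlation). Aqp4, a basolateral water channel, differed by 0.45 ± 0.14 (SE), with its 4 probes from 0.05 to 0.71, and Rhbg, an ammonia transporter of intercalated cells, by 0.25 ± 0.10 (SE). The transcription factor gene Gata3 differed by 0.25 ± 0.12 (SE) and the water channel gene Aqp3 by 0.18 ± 0.09 (SE). Aqp2, the vasopressin-regulated water channel of principal cells, differed by −0.04 ± 0.18 (SE), with its other probe at 0.087, and this sign turned under quantile, normexp and cyclic loess normalization. No member passed over all genes or adjusted over the list alone. Within the shared slide the median was 0.13 and the adjusted camera p 0.0016.

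Blood cell and platelet markers were lower as a group with tricresyl phosphate. Of 12 measured members 10 were lower, with a median of −0.30 and an adjusted camera p of 0.00416 (adjusted p = 0.671 with an estimated correlation). Hbb, a beta globin, was at 7.52 ± 0.09 (SD, n = 3) with corn oil and 7.18 ± 0.19 (SD, n = 3) with tricresyl phosphate. Alas2, the erythroid enzyme of haem synthesis, differed by −0.34 ± 0.10 (SE), the globin gene Hbe2 by −0.34 ± 0.11 (SE), with its other probe at −0.10, and Epb42, a red cell membrane protein, by −0.31 ± 0.09 (SE). No member passed over all genes or adjusted over the list alone. Within the shared slide the median was −0.28 with an adjusted camera p of 0.1, and without tricresyl phosphate replicate 2 the adjusted p was 0.0617.

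Nuclear genes of the mitochondrial respiratory chain were lower in 38 of 41 measured members, with a median of −0.11 and an adjusted camera p of 0.00243 (adjusted p = 0.86 with an estimated correlation). Cycs, which encodes cytochrome c, differed by −0.26 ± 0.11 (SE). The complex I genes Ndufb3, Ndufa2 and Ndufs4 differed by −0.33 ± 0.15 (SE), −0.24 ± 0.09 (SE) and −0.21 ± 0.10 (SE), and the other probe of Ndufs4 was at 0.20. No member passed over all genes or adjusted over the list alone. The median lay inside the central 95% of random lists matched on signal level, from −0.14 to −0.07, and the call ended under quantile normalization, where the median was −0.01 and the adjusted p 0.966. Within the shared slide the median was −0.08 with an adjusted camera p of 0.128, and without tricresyl phosphate replicate 2 the adjusted p was 0.32.

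**Figure D2:**
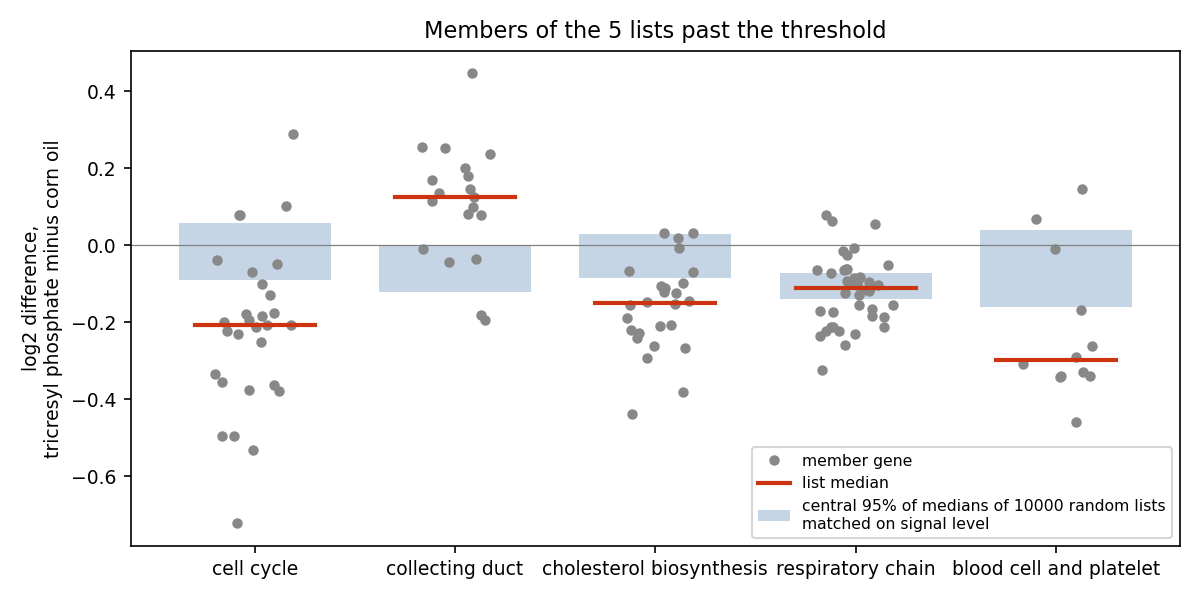
Log2 differences, tricresyl phosphate minus corn oil, of every measured member of the 5 lists past the camera threshold, with the list median as a line and the central 95% of medians of 10000 random lists matched on signal level as a band. The respiratory chain median of −0.11 lies inside its band and the other medians lie outside theirs. The random lists draw genes independently, so the band takes no account of members that vary together. Lists that did not pass camera also lay outside their bands. The angiotensin, aldosterone and sodium channel list, for example, had a median of 0.036 above an upper end of 0.005 (camera adjusted p 0.692).

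As a single value per animal, the mean level of the cell cycle, cholesterol biosynthesis and blood cell lists separated all 3 tricresyl phosphate animals from all 3 corn oil animals. The exact two-sided permutation p was 0.1 for each, the smallest that 3 against 3 animals allow. The blood cell list separated the groups only narrowly, with corn oil replicate 2 at 0.022 and tricresyl phosphate replicate 1 at 0.018. Groups were separated in this way in 7 of the 41 lists, or 17.1%, where chance gives 10%, and 4 of the 7 did not pass camera: the circadian clock, the sugar, amino acid and gluconeogenesis, the macrophage and dendritic cell and the adipocyte lists. For the respiratory chain and collecting duct lists the exact two-sided permutation p was 0.3, and the animals of both groups overlapped.

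**Figure D3:**
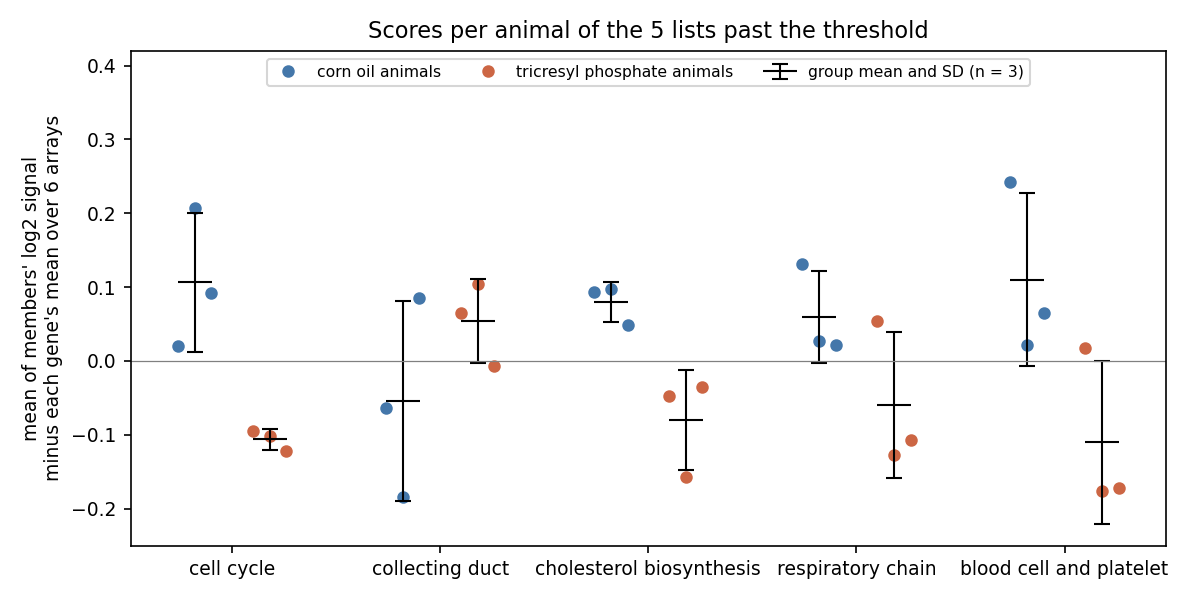
Mean of the members' log2 signal, centred on each gene's mean over the 6 arrays, for each animal (points) with the group mean and SD (n = 3), for the 5 lists past the camera threshold. Cell cycle scores ran from 0.02 to 0.21 with corn oil and from −0.12 to −0.09 with tricresyl phosphate.

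Markers of tubular injury did not pass as a group or singly in the comparison of all 6 animals. Havcr1, the kidney injury molecule, differed by −0.14 ± 0.36 (SE), Lcn2, the lipocalin released by injured tubules, by 0.15 ± 0.44 (SE), and Spp1, osteopontin, by −0.23 ± 0.21 (SE). Clu, clusterin, differed by −0.02 ± 0.26 (SE) and Cdkn1a, the p21 cell cycle inhibitor, by −0.07 ± 0.11 (SE). Of 32 measured injury markers 16 were higher and 16 lower (camera adjusted p 0.167). The list passed without corn oil replicate 2, with an adjusted p of 0.0172, and the adjusted p was 0.604 without tricresyl phosphate replicate 3 and 0.741 with an estimated correlation. Its highest mean levels were in these animals, 0.142 in corn oil replicate 2 and 0.125 in tricresyl phosphate replicate 3, which also had the highest hepatocyte markers. The signs of Clu and Cdkn1a turned under quantile, normexp and cyclic loess normalization, and so did those of Gclc and Slc22a6 below. The sign of Umod turned under normexp and cyclic loess, and that of Lcn2 with the slide as a block.

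Genes of foreign compound metabolism did not pass as groups in the comparison of all 6 animals. Cyp1a1 and Cyp2b1, the classical targets of the aryl hydrocarbon and constitutive androstane receptors, were not well above background on any array, and Cyp3a23-3a1 was so on 1 corn oil array, so they were not tested. Of 22 phase I genes 10 were higher and 12 lower (camera adjusted p 0.567, and 0.0305 without corn oil replicate 2 and tricresyl phosphate replicate 3, the 2 animals with the highest hepatocyte markers). These 2 animals also had the highest mean levels of the phase I list, 0.575 and 0.2275, so the call without them is not independent of how they were chosen. The phase I list had an adjusted p of 0.86 with an estimated correlation over all 6 animals. Among 36 NRF2 and glutathione genes 13 were higher and 23 lower (camera adjusted p 0.567), and the direction of the list turned under quantile, normexp and cyclic loess normalization. Nqo1, a quinone reductase, differed by −0.04 ± 0.22 (SE), and Gclc, a subunit of glutamate-cysteine ligase, by −0.04 ± 0.49 (SE), with its other probe at 0.15. Hmox1, haem oxygenase 1, differed by 1.16 ± 0.67 (SE), with tricresyl phosphate replicate 2 at 1.60 and the other 5 animals between −1.37 and −0.55. Of 19 conjugating enzymes 7 were higher and 12 lower (camera adjusted p 0.681), and adjusted over the list alone 1 fell, Ugt1a6, a UDP-glucuronosyltransferase, by 0.54 on the log2 scale. Of 24 esterases and neutral lipid hydrolases 17 were higher and 7 lower (camera adjusted p 0.134).

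Lipid gene groups other than cholesterol biosynthesis did not pass at the 75th percentile scaling with all 6 animals. Of 37 PPAR alpha targets and fatty acid oxidation genes 25 were higher and 12 lower (camera adjusted p 0.0747), with an adjusted p of 0.86 with an estimated correlation. The list passed with the slide as a block, which leaves out corn oil replicate 1 (0.00246), without tricresyl phosphate replicate 3 (0.00236), and under quantile (7.91e-05), normexp (6.87e-05) and cyclic loess normalization (0.000393), while the adjusted p was 0.682 without tricresyl phosphate replicate 2. Cyp4a1, a fatty acid hydroxylase induced through PPAR alpha, differed by 0.24 ± 0.22 (SE). Of 19 fatty acid synthesis genes 9 were higher and 10 lower (camera adjusted p 0.567), and of 18 cholesterol efflux and lipoprotein genes 10 were higher and 8 lower (camera adjusted p 0.28).

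Transport and hormone genes of the tubule did not pass either at the 75th percentile scaling. Slc22a6, the organic anion transporter of the proximal tubule, was at 8.19 ± 0.05 (SD, n = 3) with corn oil and 8.13 ± 0.12 (SD, n = 3) with tricresyl phosphate. Umod, the uromodulin gene of the thick ascending limb, differed by −0.12 ± 0.20 (SE), and Cyp24a1, the vitamin D 24-hydroxylase, by 0.10 ± 0.49 (SE). Camera adjusted p-values were 0.167 for 28 sugar, amino acid and gluconeogenesis genes and 0.692 for 30 organic ion and drug transporters. They were 0.597 for 33 endocytic receptor and lysosome genes, 0.692 for 18 angiotensin, aldosterone and sodium channel genes, and 0.589 for 16 vitamin D and phosphate genes. For 15 androgen and sex dependent genes the value was 0.567. The endocytic and lysosome list, with 17 members higher and 16 lower, passed in the higher direction under quantile (0.0166), normexp (0.0152) and cyclic loess normalization (0.0335), and its adjusted p was 0.86 with an estimated correlation.

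Stress, immune and matrix lists lay above the threshold with all 6 animals and the filter on dim probes. Camera adjusted p-values were 0.0747 for 22 p53 and DNA damage genes, 14 of them higher, and 0.0709 for 29 interferon response genes, 24 of them lower. The interferon list passed without corn oil replicate 3 (0.000185), without tricresyl phosphate replicate 3 (0.00264) and with no filter on dim probes (0.0284), while its adjusted p was 0.86 without corn oil replicate 2, 0.744 without tricresyl phosphate replicate 2 and 0.86 with an estimated correlation. Camera adjusted p-values were 0.589 for 30 endoplasmic reticulum stress genes, 0.515 for 18 heat shock genes, 0.738 for 22 immediate early genes and 0.567 for 23 glucocorticoid responsive genes, which passed without tricresyl phosphate replicate 3 (0.0245). The glucocorticoid list had an adjusted p of 0.86 with an estimated correlation and 0.871 without corn oil replicate 2, and its direction turned without tricresyl phosphate replicate 2 (0.419). For 15 metallothionein and metal response genes the value was 0.738, for 16 circadian clock genes 0.167 (0.0489 without the 2 animals with the highest hepatocyte markers, and adjusted p = 0.671 with an estimated correlation over all 6) and for 23 hypoxia and glycolysis genes 0.807. For 25 inflammatory cytokine and complement genes it was 0.781, and for 24 extracellular matrix genes 0.767. In 14 of the 41 lists, none past the threshold, the median, the mean and the direction of the test differed in sign.

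Markers of other cell types included 20 of the proximal tubule, 14 of them lower (camera adjusted p 0.189), a list direction that turned under quantile, normexp and cyclic loess normalization, and adjusted over the list alone 1 of these fell, Acsm3. The proximal tubule list was the 1 list past the threshold with fry, with an adjusted p of 0.0111. Its camera adjusted p was 0.676 with an estimated correlation, and its median of −0.07 lay inside the central 95% of random lists matched on signal level, from −0.15 to −0.05. Of its 20 members 2 reached an unadjusted limma p under 0.05, Acsm3 with −1.47 among them. Fry was not run without Acsm3. Of 13 endothelial markers 8 were higher (camera adjusted p 0.0709, and 0.741 with an estimated correlation). The endothelial list passed under quantile (0.0406) and normexp (0.0321) normalization, without corn oil replicate 3 (0.0364) and without tricresyl phosphate replicate 3 (0.00822), while the adjusted p was 0.391 without tricresyl phosphate replicate 2. Camera adjusted p-values were 0.453 for 15 markers of the thick ascending limb and distal tubule, 0.411 for 15 of the renal medulla and 0.567 for 17 of the podocyte and mesangium. They were 0.567 for 18 macrophage and dendritic cell markers, 0.567 for 15 lymphocyte markers and 0.848 for 12 smooth muscle and fibroblast markers. For 8 adipocyte markers the value was 0.567 and for 8 adrenal markers 0.692. The 14 hepatocyte markers had a camera adjusted p of 0.458 and differed between animals of the same group. Mean centred levels were 1.21 in corn oil replicate 2 and 0.88 in tricresyl phosphate replicate 3. The other corn oil animals were at −1.20 and −0.66 and the other tricresyl phosphate animals at −0.14 and −0.10. The hepatocyte list passed without corn oil replicate 2 (0.000357), while its adjusted p was 0.86 with an estimated correlation and 0.893 without tricresyl phosphate replicate 3, and its direction turned without corn oil replicate 1 (0.862). With corn oil replicate 2 and tricresyl phosphate replicate 3 both left out, 10 lists passed camera, 6 higher and 4 lower. These were the 5 above and the phase I, PPAR alpha, circadian clock, endothelial (0.0297) and hepatocyte (0.00113) lists. The 2 animals were chosen by their hepatocyte markers, so the value of the hepatocyte list without them is not an independent test. The phase I list also had its highest mean levels in these 2 animals, so its value without them is not independent of that choice either.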

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

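Cyclic loess normalization and leaving out both animals with the highest hepatocyte markers were chosen after the data were seen. The count of 0 genes became 2 under normexp background correction followed by quantile normalization (normexp below) and 2 under a variance model with an intensity trend and robust estimation. Leaving out 1 array at a time gave 0 to 1 gene, Zp2 without tricresyl phosphate replicate 2, where it was not well above background on either remaining tricresyl phosphate array, and ENSRNOT00000040702 without tricresyl phosphate replicate 3. The count stayed at 0 under the other alternatives run, thresholds of 0.01 and 0.1 included. The count of 5 lists became 0 with an estimated correlation, 1 with fry and 10 without both animals with the highest hepatocyte markers. It ranged from 2 (without tricresyl phosphate replicate 2) to 9 (without tricresyl phosphate replicate 3) when 1 array was left out. The replicate numbers were taken only to number the animals. Same-number correlations of deviations were 0.086, −0.051 and −0.044 for replicates 1 to 3, against highest other-number values of −0.005, 0.120 and 0.060. These few correlations cannot settle whether animals of the same number shared handling. With the replicate block 0 genes and 5 lists passed, and it changed no other call. The cause of the changes named here was not tested, except where fewer arrays enter or, for the respiratory chain, where signal level was tested below. Signal over background limits the dimmest genes: the median residual SD was 0.334 in the dimmest 20% of genes and 0.107 in the brightest 20%.

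With an estimated correlation the adjusted p was 0.6712 for the cell cycle, cholesterol biosynthesis, collecting duct and blood cell lists and 0.8596 for the respiratory chain. The estimated correlation was 0.064 for cholesterol biosynthesis, 0.106 for the cell cycle, 0.136 for the collecting duct, 0.170 for blood cells and 0.538 for the respiratory chain. Apart from cholesterol biosynthesis these lie above the 0.1 that was simulated. With fry it was 0.1877 for the cell cycle and cholesterol biosynthesis, 0.6128 for the collecting duct, 0.2655 for blood cells and 0.7759 for the respiratory chain. The respiratory chain also left the threshold under quantile normalization (0.9656), normexp (0.7801), cyclic loess (0.9144) and the slide block (0.1282), and the blood cell list with the slide block (0.1002). With 1 array left out the adjusted p ranged from 0.001003 to 0.09245 for cholesterol biosynthesis, from 0.0001128 to 0.3197 for the respiratory chain and from 0.002047 to 0.1002 for blood cells. Of 16 alternatives, 14 kept the cell cycle and the collecting duct past the threshold, 13 cholesterol biosynthesis, 11 blood cells and 8 the respiratory chain. These alternatives are not separate checks. The authors' value table holds the main scaling, and the slide block equals leaving out corn oil replicate 1. Every alternative that kept a call used camera at the preset correlation, and the estimated correlation and fry kept none of these lists.

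Of 36 lists that did not pass, 10 passed under some alternative, 0 of them with the other direction. Of 704 values of 44 named genes, 45 over 10 genes had the other sign, with 0 past the threshold, and 1 gene, Galnt3, passed under an alternative. Its log2 difference ranged from −1.21 to −1.03. Genes with the other sign (log2 difference) and lists with the other direction (adjusted p) follow by setting. Quantile normalization gave Gclc 0.054, Clu 0.044, Cdkn1a 0.012, Slc22a6 0.041 and Aqp2 0.08, and NRF2 0.816, heat shock 0.816, metallothionein 0.816, hypoxia 0.453 and proximal tubule 0.716. Normexp gave Gclc 0.039, Clu 0.031, Cdkn1a 0.022, Slc22a6 0.054, Umod 0.015 and Aqp2 0.0905, and NRF2 0.95, heat shock 0.808, metallothionein 0.792, inflammatory 0.95, hypoxia 0.435 and proximal tubule 0.692. Cyclic loess gave Gclc 0.037, Clu 0.038, Cdkn1a 0.0082, Slc22a6 0.087, Umod 0.018 and Aqp2 0.073, and NRF2 0.914, heat shock 0.986, metallothionein 0.659, hypoxia 0.479 and proximal tubule 0.619. Without the filter on dim probes these were immediate early 0.881, drug transporters 0.881 and adrenal 0.879. The mean of a gene's probes gave Gclc 0.052 and Aqp2 0.022. The slide block gave Lcn2 −0.034 and Aqp2 0.0092, and fatty acid synthesis 0.971, extracellular matrix 0.633, drug transporters 0.783, androgen 0.971, lymphocyte 0.971 and hepatocyte 0.862. Fry gave 0.999 for the endoplasmic reticulum stress, immediate early, inflammatory, extracellular matrix, aldosterone, vitamin D, drug transporter, endocytic, podocyte and adrenal lists. Without both animals with the highest hepatocyte markers these were Gclc 0.068, Havcr1 0.16, Lcn2 −0.026, Clu 0.28 and Cyp24a1 −0.14, and heat shock 0.961, metallothionein 0.628, vitamin D 0.628, endocytic 0.778, thick ascending limb 0.316, adipocyte 0.948 and smooth muscle 0.158.

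With 1 array left out at a time, log2 differences that crossed 0 ranged from −0.23 to 0.11 for Nqo1, −0.39 to 0.41 for Gclc, −0.36 to 0.28 for Havcr1, −0.14 to 0.58 for Lcn2, −0.22 to 0.22 for Clu and −0.13 to 0.021 for Cdkn1a. They ranged from −0.42 to 0.42 for Cyp24a1, −0.25 to 0.059 for Umod and −0.18 to 0.10 for Aqp2. Adjusted p-values of lists whose direction turned ranged from 0.194 to 0.971 for fatty acid synthesis, 0.1 to 0.825 for heat shock, 0.121 to 0.946 for immediate early, 0.0245 to 0.871 for glucocorticoid, 0.517 to 0.979 for metallothionein and 0.165 to 0.862 for inflammatory genes. They ranged from 0.229 to 0.982 for extracellular matrix, 0.206 to 0.862 for vitamin D, 0.115 to 0.928 for drug transporters, 0.391 to 0.871 for endocytic, 0.678 to 0.961 for hypoxia and 0.193 to 0.971 for androgen genes. For cell types they ranged from 0.0772 to 0.946 for thick ascending limb, 0.206 to 0.971 for lymphocyte, 0.548 to 0.894 for adrenal, 0.000357 to 0.893 for hepatocyte and 0.193 to 0.893 for smooth muscle.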

Other observations

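Several genes differed widely between animals of the same group. They were chosen after their values were seen, and the adjusted limma p of each between the groups lay above the threshold. Cyp2c24, a cytochrome P450, was not well above background in tricresyl phosphate replicates 1 and 3 and was between −1.01 and 0.62 in the other 4 animals. Zp2, a zona pellucida gene, was not well above background in the same 2 animals and was between −2.01 and −1.41 in the others. Slpi, a secreted protease inhibitor, was at −4.59 and −4.03 in tricresyl phosphate replicates 1 and 2 and between 0.44 and 1.31 in the other 4. Gal, the galanin gene, spanned a 2046-fold range over the 6 animals, with corn oil replicate 3 and tricresyl phosphate replicates 2 and 3 above 3 and the others below −4. Adtrp was at −1.98 in corn oil replicate 3 and between 2.98 and 4.03 in the others.

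Other genes with groups that did not overlap, also chosen after their values were seen, had adjusted limma p-values of 0.811. Fabp4, a fatty acid binding protein of adipocytes and endothelium, differed by 1.73 ± 0.46 (SE), and the endothelial genes Flt1, Tie1 and Esam by 0.56 ± 0.15 (SE), 0.25 ± 0.08 (SE) and 0.25 ± 0.09 (SE). Plvap, an endothelial gene of fenestral diaphragms, differed the other way, by −0.17 ± 0.09 (SE). Cxcl13, a B cell chemokine, differed by −1.12 ± 0.29 (SE). In the PPAR alpha list, Cyp4a3 differed by −1.03 ± 0.30 (SE), while 25 of its 37 measured members were higher.

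The tests below on signal level and on the noise of dim probes were chosen after the results they bear on were seen. The slide block and the estimated correlation were alternatives fixed before the data were examined, but were taken up as tests of the explanations below only after their values were seen. Tests of the second liver list and of other splits were set before their results.

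The cell cycle list was lower with tricresyl phosphate. A difference between arrays that depends on signal level is argued against by an adjusted camera p of 2.212e-06 after cyclic loess normalization and by a median of −0.21, below the band of −0.09 to 0.06 of lists matched on level. The slide of corn oil replicate 1 is argued against by that animal's mean list level of 0.02, the lowest with corn oil. The other corn oil animals were at 0.21 and 0.09. Within the shared slide the median stayed lower, at −0.27. The adjusted p of 4.105e-07 there came from camera at the preset correlation. Members that vary together between animals stay open, since the adjusted p was 0.6712 with an estimated correlation and 3 against 3 animals cannot give an exact p under 0.1. Over the alternatives the adjusted p ran from 4.105e-07 to 0.6712. An effect of tricresyl phosphate on proliferation in the cortex and this shared variation cannot be told apart here.

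The respiratory chain list was lower with tricresyl phosphate, and its members are bright on these arrays. In the brightest 20% of all genes the median difference was −0.07 and 76.0% were lower, against −0.003 in the middle 20%. The dimmest 20% also had a median of −0.08, with 59.7% lower, so the difference did not fall steadily with brightness. A candidate explanation is a difference between arrays that depends on signal level: after cyclic loess the median moved from −0.11 (quartiles −0.18 and −0.06) to −0.01 (quartiles −0.06 and 0.04) and the adjusted p to 0.9144. The call ended because the shift itself went, and the list lay inside the band of lists matched on level before that. Over the alternatives the adjusted p ran from 0.0001128 to 0.9656, and an effect of the treatment on these genes was not tested apart from that trend.

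Hepatocyte markers were high in corn oil replicate 2 and tricresyl phosphate replicate 3. Of the 14 measured markers 9 had these animals as their 2 highest. Alb, the albumin gene, was at 2.62 and 2.21 in these animals and between −2.47 and −0.11 in the other 4, a 34.1-fold range, and Ttr, the transthyretin gene, spanned a 42.5-fold range. Noise of dim probes is argued against by a median SD of 1.141 over the markers, above 0.239, the upper end of the central 95% of lists matched on level. The list was taken up after its spread was seen, so this SD gives the size of that spread and is not an independent test. Liver RNA in some samples stays open: in a second list of liver genes, 13 of 30 measured members, or 43.33%, had these animals as their 2 highest, where chance gives 6.67% and all genes gave 5.14%, and this lies between the bounds of 20% and 50% set beforehand, while 9 of the 30 were above the 75th percentile signal on every array, so this tissue may also express them. Both groups hold such an animal, so these 2 high levels do not follow treatment. The remaining animals did divide by group, with mean centred levels of −1.20 and −0.66 for corn oil and −0.14 and −0.10 for tricresyl phosphate. Whether this division follows treatment cannot be told from so few animals, left after a choice made on the same markers. Other biological explanations were not tested.

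Other splits of the 6 animals into 3 and 3 number 10 with the real one, too few for a share under 0.05. For genes the real split gave 0 and the highest other 4. With a count of 0, 10 of the 10 splits give at least as many whatever the data, so this count says nothing about chance. For lists at the preset correlation the real split gave 5 and the highest other 10. With the real one included, 7 of the 10 splits gave at least 5 lists, so this count does not set the real split apart.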
